A study of Marchantia polymorpha with 18 samples.

How the data were processed

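Messenger RNA of Marchantia polymorpha thallus was sequenced in 18 libraries, made from 26-day-old plants of the wild type (WT) and of mpglr-7, a CRISPR deletion mutant of MpGLR, the glutamate receptor-like channel gene of this liverwort. Each genotype gave 3 groups of 3 libraries. Intact libraries came from plants that were not wounded. Damaged libraries came from lobes crushed with forceps, 2 lobes per plant. Systemic libraries came from neighbouring lobes of the same wounded plants that were left whole. Tissue was taken 2 h after wounding, and each library pooled tissue of 8 plants, with 3 independent biological replicates per group per the labels. Libraries were made from oligo-dT selected mRNA and sequenced on a DNBSEQ instrument, per the labels' protocols.

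The authors deposited 1 table of FPKM values (fragments mapped per kilobase of transcript, scaled to the mapped fragments of each library), per the file headers, with 1 value per transcript model and library. HISAT2 and HTSeq are named, without versions, per the submitters' processing notes. The genome build, the program that made the FPKM values and any filter are not given in the sources used here. The deposited FPKM columns do not sum to the same total, and their sums ranged from 656560 to 727248. Read depth is unknown, because FPKM values hold no counts. An estimate from the smallest steps of genes of low FPKM gave 0.917 to 1.04 for the depth relative to WT intact replicate 1. It kept only ratios close to 1, from as few as 10 genes per library, so it could not show a large difference in depth. No interval or detection limit from counts is given.

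The 21152 transcript models, 244 of them at 0 in every library, were summed by gene identifier to 16731 genes, of which 2814 had more than 1 model. Symbols came from a table of gene names for the assembly MpTak2_v7.1, used only for names and for which loci neighbour each other. Of 16615 autosomal identifiers, 16096 were in that table, as were 31 of the 35 whose number does not end in 0, and 2942 genes had a symbol. Another 60 identifiers lay on the V chromosome and 53 were unplaced. No symbol of the name table contains GLR, so the FPKM of the mutated gene is not analysed here, and the genotype labels were not checked from it.

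FPKM values were compared as log2(FPKM + 1), computed here from the deposited FPKM. The added 1 makes fold changes of genes of low FPKM smaller than the ratio of their FPKM. Genes with an FPKM of at least 1 in at least 3 of the 18 libraries were kept, which left 11778. The moderated test of limma 3.58.1 in R 4.3.3 was fitted to the 6 group means of all 18 libraries, with a mean-variance trend and no replicate block, with 15.9 degrees of freedom in all. Tests were 2-sided. Benjamini-Hochberg adjustment was made over the genes tested in each comparison, with a threshold of 0.05. The 11 comparisons were damaged and systemic tissue against intact tissue and damaged against systemic tissue in each genotype, mpglr-7 against WT in each of the 3 tissue states, and the differences between genotypes in the damaged and in the systemic response (interactions). "Higher" and "lower" refer to the group named first. Values are mean FPKM ± SD with n = 3 libraries per group, log2 changes have their standard error (SE), and all adjusted p-values of genes are from limma.

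Gene lists were written as patterns of names before the data were examined, as were the tests, thresholds, most other settings and the rule for named genes. The patterns were turned into symbol lists when the name table was seen, before any comparison was tested; cupin genes were then given a list of their own. This gave 29 lists, 28 of them with at least 3 tested genes. Lists that would have needed product names (photosynthesis, ribosomal proteins, ubiquitin ligases, sugar transport, organelle genes) are not analysed here. List genes were counted as higher, lower or not passing, both over all genes and adjusted over the list alone. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01 and again with an estimated correlation, and by fry, which tests a list's own genes without comparing them with others. Adjusted p-values of lists are from camera with the preset correlation unless an estimated correlation is named, and are adjusted over the 28 lists of a comparison.

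The rule for named genes took, for each comparison, the 10 largest positive and 10 largest negative log2 changes among genes with a symbol that passed and whose libraries did not overlap between groups, up to 2 genes without a symbol in each direction, and up to 4 passing genes of smallest p from each list. The text prints a part of these, and MpRSL1 as the 1 gene of its list; every other gene it names is said to have been chosen after its values were seen.

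A held-out response index compared genotypes without measuring WT in the libraries that chose the genes. Genes passing between WT damaged and intact tissue were chosen without replicate k, and their mean damaged minus intact difference was taken in replicate k of each genotype, with an exact 2-sided permutation test of 3 against 3 values, whose smallest possible p is 0.1. Correlations of responses were taken across genes, which are not independent replicates. Where responses shared intact libraries, 20 simulations without any response gave the covariance that sharing alone produces in libraries otherwise independent.

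From the data, not from the labels, same-numbered libraries deviated together within a genotype: correlations of their deviations from the group mean were 0.16 to 0.49 in 6 of 6 pairs of groups, above a cut of 0.1. For WT intact and systemic tissue, different numbers reached 0.19, against a lowest same-number value of 0.18. Between genotypes 1 of 3 pairs of the same tissue state passed the cut, the intact groups (0.42, 0.12 and 0.68, with up to 0.38 for different numbers). The lowest same-number correlation between genotypes was -0.37. Replicate number was therefore also fitted as a block. The other settings were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, quantile normalization, upper-quartile scaling, a log2 change of at least 1, only the groups compared, and each library left out. Settings added after seeing the data were a block within genotype, median scaling, transcript models unsummed, genes with 1 model, replicate 3 of both intact groups left out, an index of 100 genes, and an index of genes chosen in mpglr-7.

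The tests were tried on simulated data of the 11778 genes, in which 66 or 68 genes had a known change of each size. These genes had a mean log2(FPKM + 1) of at least 1. Libraries were simulated as independent, without the shared deviations described above, so recovery in the real libraries may differ. In a simulated WT damaged against intact comparison, 67.6% of genes changed by a log2 of 0.5 were recovered, 93.9% of those changed by 1 and 100% of those changed by 2, and 5.4% of calls were false. In a simulated damaged interaction 29.4%, 90.9% and 100% were recovered with 7% false calls, and in a simulated systemic interaction 22.1%, 95.5% and 100% with 4.6%. Tables and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.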

Results

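The series asked what MpGLR contributes to the change of gene expression after wounding in Marchantia polymorpha. RNA was profiled in 6 groups of 3 libraries: intact, damaged and systemic thallus of WT and of the deletion mutant mpglr-7. Systemic tissue is the unwounded lobes next to the crushed ones. The mutated gene itself is not analysed here, so the genotypes are taken from the labels. Across the 18 libraries, 11197 to 11394 genes had an FPKM of at least 1, and the 10 genes of highest FPKM held 12.42% to 17.56% of it. Read depth is unknown. The first principal component held 75.8% of the variance and set the 6 damaged libraries apart from the other 12. The second held 5.2%, and on it replicate 3 of WT intact (-21.87) and of mpglr-7 intact (-18.28) lay lowest.

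**Figure D1:**
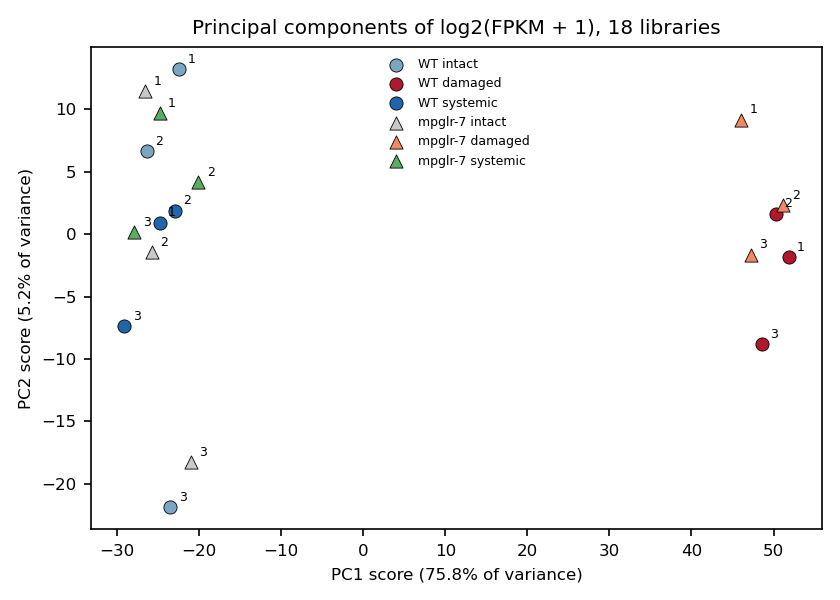
Scores of the 18 libraries on the first and second principal components of log2(FPKM + 1), with circles for WT, triangles for mpglr-7 and replicate numbers beside the points. The 6 damaged libraries lie apart on the first component (75.8% of the variance), and replicate 3 of both intact groups lies lowest on the second (5.2%).

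To describe the local wound response of WT, crushed lobes were compared with lobes of intact plants 2 h after wounding. Genes of dirigent proteins, which guide the coupling of phenolic radicals, were among those that rose most. MpDIR42 (Mp5g16470) went from 0.207 ± 0.358 to 153 ± 23.8 FPKM (log2 change 7.03, SE 0.474, adjusted p 5.23e-09), and MpDIR39 (Mp5g16510) from 3.19 ± 1.20 to 476 ± 35.7 (6.87, SE 0.581, adjusted p 7.43e-08). The transcription factor genes MpBHLH4 (5.72, SE 0.316) and MpERF21 (4.80, SE 0.128), the cytochrome P450 gene MpCYP815A1 (4.98, SE 0.129) and the lipoxygenase gene MpLOX2 (3.69, SE 0.159) also rose. The pectin methylesterase gene MpCE8.10 (Mp5g03920) had the largest decrease, from 89.5 ± 30.5 to 11.4 ± 0.667 FPKM (-2.80, SE 0.284, adjusted p 5.83e-07). Of 11778 genes tested, 2175 were higher and 3720 lower (50.05%), with 745 higher and 301 lower by at least 2-fold.

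Among genes with a symbol, the 10 largest increases ran from 4.98 to 7.03 and included MpDIR41 (6.35), MpDIR61 (6.14), MpDIR38 (5.64), MpDIR65 (5.40), MpBHLH51 (5.35) and MpPR15c (5.01). Mp5g16450, which has no symbol, rose by 7.21. The 10 largest decreases included MpCYP78-like1 (-2.41), the peroxidase gene MpPOD7 (-2.11), the LysM protein gene MpLYP (-2.08), the transporter gene MpABC24 (-2.05) and MpCUS (-1.88). In the name table, 6 of these dirigent genes stand in a stretch of 8 loci that also holds Mp5g16450 and the polyphenol oxidase gene MpPPO28 (4.50). Neighbouring family members can share reads, and how such reads were divided is not given in the sources used here, so the values of single members are uncertain.

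Lists of oxylipin, phenolic and defence genes were higher. Counts adjusted over the list alone were the same for 17 of the 28 lists and are given where they differed. Of 17 lipoxygenase and allene oxide synthase genes, which act in oxylipin synthesis, 10 rose and 3 fell (list adjusted p 0.00142, adjusted p = 0.258 with an estimated correlation). MpCYP74N2 reached 1215 ± 56.0 FPKM from 160 ± 5.72 (2.92), and MpLOX4 rose by 4.03. Of 64 phenylpropanoid and flavonoid genes 30 rose and 14 fell, or 34 and 14 adjusted over the list alone (1.29e-05, adjusted p = 0.258 with an estimated correlation). They included the 4-coumarate-CoA ligase genes Mp4CL2 (3.61; 38.8 ± 5.63 to 482 ± 22.5 FPKM) and Mp4CL1 (3.11) and the chalcone synthase-like gene MpPKS/CHS21 (4.68). Of 49 dirigent genes 26 rose and 7 fell, or 27 and 7 adjusted over the list alone (2.32e-07, adjusted p = 0.12 with an estimated correlation), with MpDIR17 at 1799 ± 174 FPKM against 181 ± 43.2. Of 33 polyphenol oxidase genes, whose enzymes oxidise phenols, 12 rose and 9 fell (0.0126, adjusted p = 0.328 with an estimated correlation), among them MpPPO22 (3.58) and MpPPO20 (3.88). Of 18 pathogenesis-related genes 7 rose and 4 fell (0.0306, adjusted p = 0.426 with an estimated correlation). Among 50 antioxidant and glutathione transferase genes 19 rose, such as MpMDHAR2 (1.44) and MpGST30 (1.81), and 11 fell (0.0367, adjusted p = 0.328 with an estimated correlation).

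Among regulators, 11 of 12 WRKY genes rose and 0 fell (2.56e-06, adjusted p = 0.0822 with an estimated correlation). MpWRKY7 went from 0.493 ± 0.150 to 4.67 ± 0.592 FPKM and MpWRKY11 from 247 ± 10.1 to 575 ± 33.2. Of 7 NAC genes 5 rose and 1 fell (0.00606, adjusted p = 0.328 with an estimated correlation). Of 26 MAP kinase cascade genes 10 rose, such as MpMAPKKK10 (2.66) and MpMKK3 (0.89), and 7 fell (0.0482, adjusted p = 0.611 with an estimated correlation). Of 72 abscisic acid and late embryogenesis abundant (LEA) genes, the latter coding for proteins known from drying tissue, 26 rose and 4 fell (6.33e-05, adjusted p = 0.559 with an estimated correlation). MpLEA-like11 rose by 1.91 and MpLEA-like33 by 2.04. MpJAZ, a repressor of the Marchantia jasmonate pathway, rose by 1.97 (SE 0.182, adjusted p 2.01e-07). The receptor gene MpCOI1 fell (-0.57, SE 0.079, adjusted p 1.89e-05). The jasmonate signalling list of 3 genes, with 1 higher and 1 lower, did not pass (0.556).

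The cell cycle, histone and peroxidase lists were lower. Of 20 cell cycle genes 18 fell and 0 rose (6.33e-05, adjusted p = 0.328 with an estimated correlation), including MpCDKA (-0.60) and the replicative helicase genes MpMCM6 (-1.20; 2.81 ± 0.381 to 0.653 ± 0.0635 FPKM), MpMCM2 (-1.08) and MpMCM7 (-1.08). Of 25 histone genes 19 fell and 0 rose, or 21 and 0 adjusted over the list alone (7.31e-05, adjusted p = 0.426 with an estimated correlation), with MpH3.1d at -1.30. Of 83 class III peroxidase genes 53 fell and 5 rose, or 56 and 5 adjusted over the list alone (0.000128, adjusted p = 0.426 with an estimated correlation). MpPOD88 fell (-1.40) and MpPOD164 rose from 431 ± 69.6 to 1141 ± 61.1 FPKM. The auxin influx carrier gene MpAUX1 fell from 103 ± 8.68 to 35.6 ± 4.42 FPKM and the auxin synthesis gene MpYUC2 by 1.09 (log2).

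The remaining lists did not pass. Higher and lower counts were 7 and 6 of 20 AP2/ERF genes (0.0543), 7 and 10 of 41 MYB genes (7 and 9 adjusted over the list alone; 0.913), and 7 and 15 of 35 bHLH genes (8 and 15; 0.895). They were 4 and 1 of 12 terpene synthase-like genes (0.177), 3 and 3 of 9 calcium signalling genes (0.625), 2 and 2 of 6 heat shock genes (0.556), 7 and 6 of 19 protein phosphatase 2C genes (0.464), and 25 and 22 of 75 cytochrome P450 genes (27 and 24; 0.124). They were 14 and 27 of 66 cell wall genes (14 and 28; 0.595), 1 and 10 of 37 cupin genes (1 and 8; 0.569), 9 and 30 of 61 receptor-like kinase genes (9 and 32; 0.131), and 6 and 12 of 28 auxin genes (7 and 12; 0.556). Of the cell type markers, 1 of 5 oil body cell genes rose and 1 fell (0.895), 0 of 3 reproductive organ genes rose and 1 fell (0.229), and MpRSL1, the 1 gene of the rhizoid list, was at -0.12 (SE 0.114, adjusted p 0.398). MpC1HDZ, a regulator of oil body cells, rose from 20.2 ± 7.49 to 73.8 ± 1.10 FPKM. The test pointed up while the median was negative for the bHLH (-0.066), cytochrome P450 (-0.093) and oil body (-0.114) lists.

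Among genes of mean FPKM of at least 5, the peroxidase list did not pass (0.329, range 1.26e-05 to 0.329 over 6 alternatives) nor did the pathogenesis-related list (0.718, range 0.0269 to 0.718). The antioxidant (0.0812, range 0.0372 to 0.0812) and MAP kinase (0.0549, range 0.0258 to 0.0549) lists were lost with quantile normalization, and the polyphenol oxidase list with median scaling (0.0603, range 0.000623 to 0.0603). By fry, 24 of the 28 lists moved 1 way on balance. With median scaling 2777 genes were higher and 2888 lower (49% higher, against 36.9% of the calls above).

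**Figure D2:**
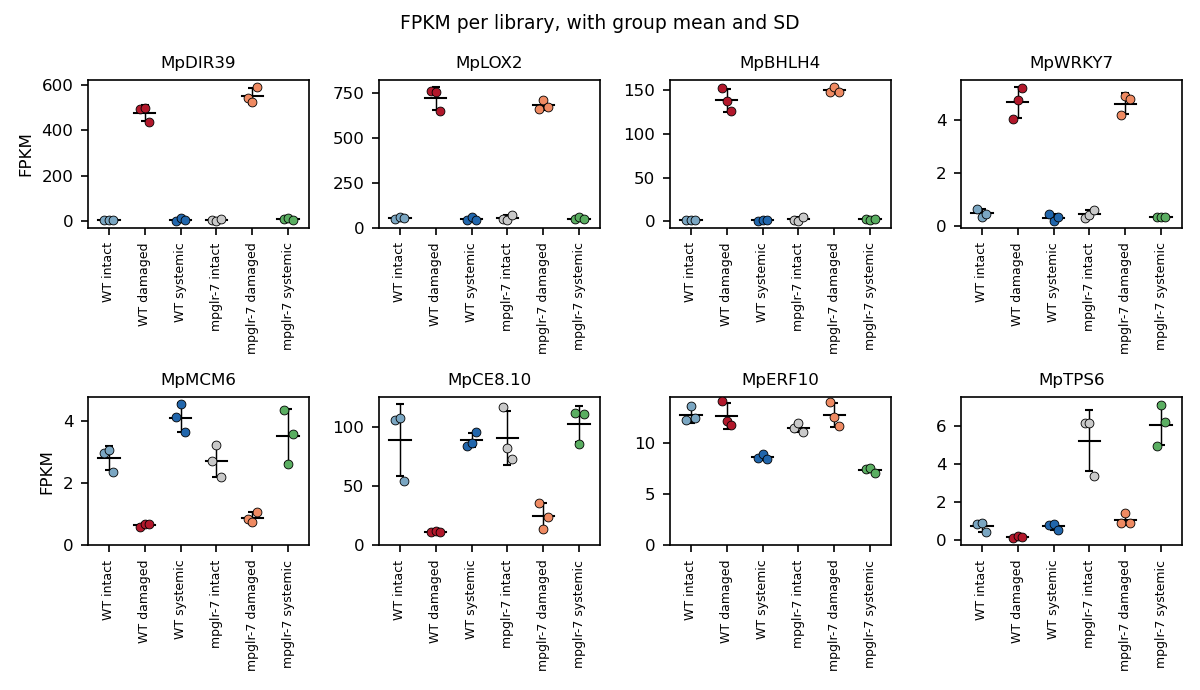
FPKM of 8 genes in each of the 18 libraries (points), with the group mean (long line) and SD (bars), n = 3. MpDIR39 reached 476 ± 35.7 FPKM in WT damaged and 553 ± 35.1 in mpglr-7 damaged tissue, and MpERF10 had its lowest values in systemic tissue of both genotypes.

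To ask whether the wound response reached unwounded lobes of WT, systemic tissue was compared with intact tissue. Few genes passed the threshold, and most of them were lower. The transcription factor gene MpERF11 (Mp7g17020) fell from 5.11 ± 0.884 to 1.93 ± 0.319 FPKM (-1.05, SE 0.183, adjusted p 0.0119), and the peroxidase genes MpPOD156 (133 ± 16.9 to 75.7 ± 5.30 FPKM; -0.80, SE 0.142) and MpPOD167 (417 ± 47.3 to 254 ± 12.1; -0.71, SE 0.135) fell as well. MpERF10 (-0.52, SE 0.078, adjusted p 0.00535), MpWRKY9 (-0.57), MpBHLH52 (-0.59), the phosphatase gene MpPP2C_C2 (-0.59) and MpCYP707A (-0.68), whose enzyme class inactivates abscisic acid, were also lower. Of the genes that rose, MpCYP759B3 (0.51, SE 0.095, adjusted p 0.0189) was the only one with a symbol, and Mp2g15440 rose by 1.10 (SE 0.118, adjusted p 0.000451). Mp1g03750 had the largest decrease, from 61.1 ± 11.7 to 17.96 ± 1.34 FPKM (-1.70, SE 0.197, adjusted p 0.00088).

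In all, 11 genes were higher and 113 lower, 2 and 10 of them by at least 2-fold, and 1582 had an unadjusted p under 0.05 (limma), against 589 expected by chance. MpJAZ, chosen after its value was seen, had a log2 change of -0.004 (adjusted p 0.994). Of the genes lower in WT systemic tissue 52 were also lower in damaged tissue and 24 were higher there, with 35.7 and 20.9 expected if calls were independent. Both comparisons use the WT intact libraries, and the counts that sharing alone would give were not computed.

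With the replicate number as a block across genotypes 294 genes passed (36 higher, 258 lower), and with a block within genotype, which follows the pairing and was chosen after seeing the data, 335 (39 higher, 296 lower). The count rested on single libraries: it was 24, 50 and 287 without WT intact replicate 1, 2 and 3, and 98, 32 and 18 without WT systemic replicate 1, 2 and 3. It was 352 without replicate 3 of both intact groups, a choice made after seeing the data. WT systemic replicate 3 had the highest FPKM sum of the 18 libraries (727248) and the highest share in its 10 top genes (17.56%). The median log2 change over all genes was -0.049, and -0.006 without this library, where 2 of the 18 calls were higher. Without WT intact replicate 1 the median was -0.023. Of the 18 genes named by the rule, 11, 10 and 2 lost their call without WT intact replicate 1, 2 and 3, and 5, 11 and 12 without WT systemic replicate 1, 2 and 3, with adjusted p up to 0.159. In a fit of only the groups compared 17 of the 18 lost their call (adjusted p up to 0.207), and 5 genes passed in all. The higher share, 8.9%, was 29.2% with quantile normalization (26 of 89), 29.8% with upper-quartile scaling (25 of 84) and 20.2% with median scaling (23 of 114).

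As lists, 3 were higher and 8 lower in WT systemic tissue, and none kept its call with an estimated correlation. By fry 7 of the 28 lists passed. Histone genes (median 0.18; 3.89e-09, adjusted p = 0.269 with an estimated correlation) and cell cycle genes (0.17; 6.37e-05, adjusted p = 0.369 with an estimated correlation) pointed up, though 0 of their members passed over all genes, and 0 and 1 did adjusted over the list alone. Terpene synthase-like genes pointed up as well (0.21; 0.00164, adjusted p = 0.184 with an estimated correlation), with 0 members passing, or 2 adjusted over the list alone. Peroxidase genes pointed down (-0.31; 3.2e-05, adjusted p = 0.369 with an estimated correlation), with 2 lower, or 3 adjusted over the list alone. WRKY genes (-0.28; 0.000221, adjusted p = 0.184 with an estimated correlation) had 1 lower, or 4 adjusted over the list alone. bHLH genes (-0.15; 0.00191, adjusted p = 0.209 with an estimated correlation) had 1 lower, or 6 adjusted over the list alone. Receptor-like kinase (0.00486), phosphatase 2C (0.00844), oxylipin (0.00973), calcium (0.0143) and NAC (0.0253) genes also pointed down, with adjusted p = 0.587, 0.369, 0.333, 0.369 and 0.369 with an estimated correlation. Among genes of mean FPKM of at least 5 the cell cycle (0.185, range 0.000123 to 0.185 over 6 alternatives), oxylipin (0.0519, range 0.00337 to 0.0519) and NAC (0.0519, range 0.016 to 0.0519) calls were lost. Cell wall genes (0.104) passed as lower with quantile (0.016), upper-quartile (0.0182) and median scaling (0.0408). Over the 28 lists together, 2 genes were higher and 11 lower, or 14 and 47 adjusted over the list alone.

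To set crushed tissue against unwounded tissue of the same plants, damaged lobes were compared with systemic lobes of WT. MpDIR39 (6.74), MpDIR42 (6.10), MpBHLH4 (5.98, adjusted p 2.29e-10) and MpERF21 (5.09, adjusted p 5.79e-14) were among the genes that rose most, and MpLOX4 (4.37), MpLOX2 (3.84) and MpWRKY9 (1.54) rose too. MpCE8.10 (-2.85), MpCYP78-like1 (-2.60), MpPOD7 (-2.48), MpMCM6 (-1.63, adjusted p 6.94e-08) and the auxin synthesis gene MpTAA (-1.08) fell. MpNINJA, an adaptor of jasmonate repressors, rose by 0.28 (adjusted p 0.0138). In total 2559 genes were higher and 3280 lower (49.58%), with 876 and 223 by at least 2-fold. This test did not pair libraries. With the replicate number as a block across genotypes 6342 genes passed, and with the block within genotype, chosen after seeing the data, 6496. Of the 2559 higher genes 2044 were also higher against intact tissue, with 472.6 expected if calls were independent, though both comparisons share the damaged libraries. The share of calls that were higher was 43.8%, 33.2% with upper-quartile scaling (2250 higher, 4517 lower) and 50% with median scaling (2961 higher, 2956 lower).

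Of the 28 lists, 13 passed. WRKY genes had 11 of 12 higher (2.24e-07, adjusted p = 0.0463 with an estimated correlation). Higher lists lost with an estimated correlation were dirigent (4.41e-07, adjusted p = 0.159 with an estimated correlation), ABA and LEA (7.25e-05; 0.635), phenylpropanoid (0.000159; 0.267), oxylipin (0.000344; 0.159), NAC (0.00292; 0.267), polyphenol oxidase (0.0109; 0.3), AP2/ERF (0.0192; 0.357), MAP kinase (0.0205; 0.635) and pathogenesis-related genes (0.0216; 0.409), the last value of each bracket being the adjusted p with an estimated correlation. Lower lists were histone (2.24e-07; 0.267), cell cycle (9.95e-07; 0.267) and peroxidase genes (0.0192; 0.635), read in the same way. Histone genes had 22 of 25 lower and cell cycle genes 19 of 20. The peroxidase list was lost with quantile normalization (0.0618) and upper-quartile scaling (0.0906), and with the pathogenesis-related list among genes of mean FPKM of at least 5 (0.677 each; peroxidase 0.00563 to 0.677 over 6 alternatives, pathogenesis-related 0.00958 to 0.677). Over the 28 lists 290 genes were higher and 236 lower, or 294 and 241 adjusted over the list alone.

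**Figure D3:**
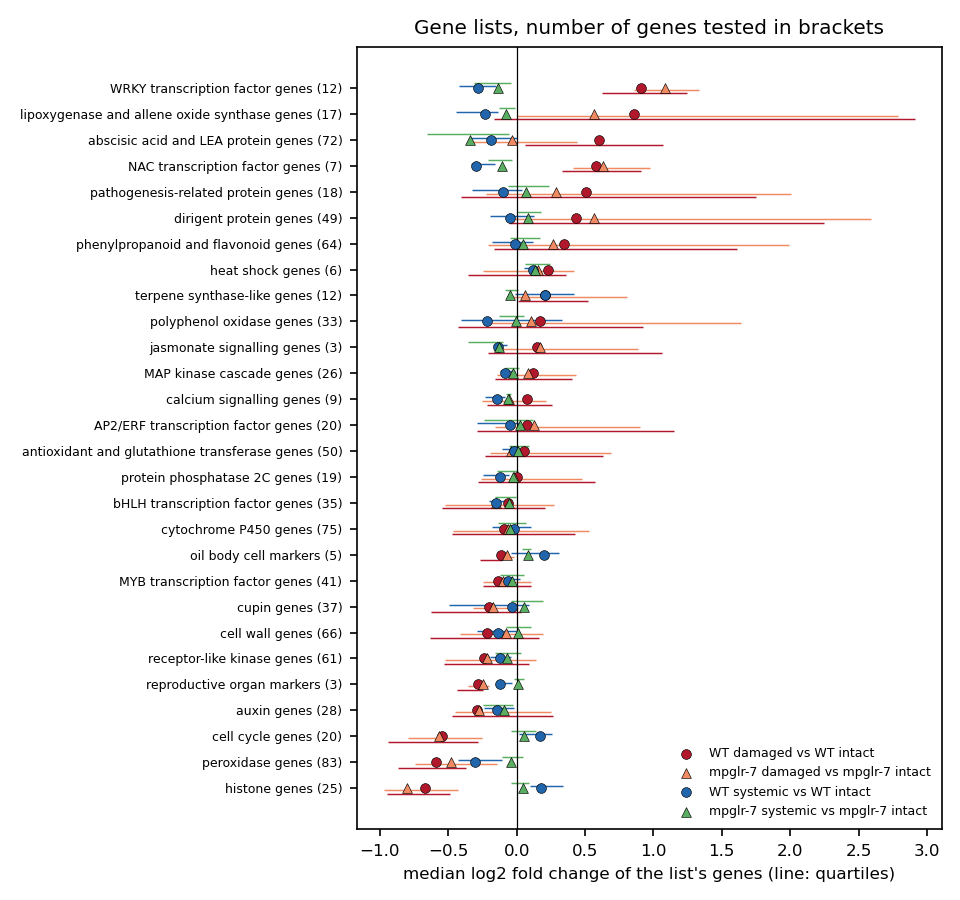
Median log2 fold change of the tested genes of each of the 28 lists (points) with quartiles (lines), for damaged and systemic against intact tissue in WT (circles) and mpglr-7 (triangles). WRKY genes lie highest in damaged tissue of WT (0.91) and mpglr-7 (1.09), and histone genes lowest (-0.67 and -0.80).

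To follow the same local response in the deletion mutant, damaged and intact tissue were compared in mpglr-7. The dirigent genes MpDIR39 (3.83 ± 3.86 to 553 ± 35.1 FPKM; 7.17, SE 0.581, adjusted p 4.83e-08), MpDIR42 (6.68) and MpDIR41 (6.27) rose, as did MpBHLH4 (5.67, SE 0.316), MpPPO31 (5.13), MpPKS/CHS21 (4.96, SE 0.14), MpERF21 (4.80, SE 0.128), MpCYP815A1 (4.59) and MpLOX2 (3.63, SE 0.159). MpJAZ rose by 1.60 (adjusted p 2.45e-06) and MpCOI1 fell (-0.49, adjusted p 8.67e-05). MpCYP78-like1 (-1.97), MpCE8.10 (-1.91, SE 0.284), MpABC24 (-1.79), MpTPS6 (-1.58; 5.23 ± 1.62 to 1.04 ± 0.294 FPKM) and MpBHLH21 (-1.49) had the largest decreases among genes with a symbol. In total 2090 genes were higher and 3291 lower (45.69%), with 756 and 157 by at least 2-fold. With median scaling 2667 were higher and 2578 lower, so that 50.8% of calls were higher against 38.8%.

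Of the 28 lists, 11 passed. All 12 WRKY genes but 1 rose (1.7e-07, adjusted p = 0.0441 with an estimated correlation), with MpWRKY10 at 2.34 and MpWRKY12 at 1.68. Of 49 dirigent genes 27 rose and 3 fell (4.8e-09, adjusted p = 0.0638 with an estimated correlation). Of 64 phenylpropanoid genes 29 rose and 12 fell, or 29 and 13 adjusted over the list alone (2.69e-05, adjusted p = 0.227 with an estimated correlation). Of 17 oxylipin genes 9 rose and 3 fell (0.000354, adjusted p = 0.145 with an estimated correlation). Polyphenol oxidase (0.000751), NAC (0.00365), pathogenesis-related (0.0048) and AP2/ERF (0.0161) genes were higher, with adjusted p = 0.227, 0.227, 0.301 and 0.301 with an estimated correlation. Histone genes had 21 of 25 lower (1.13e-05, adjusted p = 0.301 with an estimated correlation), cell cycle genes 14 of 20, or 15 adjusted over the list alone (0.000354, adjusted p = 0.317 with an estimated correlation), and peroxidase genes 43 of 83 (0.01, adjusted p = 0.647 with an estimated correlation). Of 72 ABA and LEA genes 11 rose and 4 fell, or 10 and 4 adjusted over the list alone, and the list did not pass (median -0.032; 0.181). Over the 28 lists 239 genes were higher and 248 lower, or 242 and 252 adjusted over the list alone. Among genes of mean FPKM of at least 5, the peroxidase (0.861, range 0.00154 to 0.861 over 6 alternatives) and pathogenesis-related (0.475, range 0.00371 to 0.475) lists did not pass.

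In systemic tissue of mpglr-7, compared with intact tissue to ask for a response at a distance, MpERF10 fell from 11.5 ± 0.470 to 7.39 ± 0.244 FPKM (-0.58, SE 0.078, adjusted p 0.00973) and MpASLBD17 fell (-0.51, SE 0.085, adjusted p 0.0329). Mp1g03750 fell (-1.38, SE 0.197, adjusted p 0.0128) and Mp2g15440 rose by 0.88 (SE 0.118, adjusted p 0.00973). In total 1 gene was higher and 6 were lower, and 822 had an unadjusted p under 0.05 (limma), against 589 expected by chance. The 1 higher gene and 5 of the 6 lower genes were also called in WT systemic tissue, with 0 and 0.1 expected if calls were independent. These expected numbers leave out that same-numbered intact libraries of the genotypes tended to deviate together (0.42, 0.12 and 0.68). With the replicate number as a block across genotypes 20 genes passed (4 higher, 16 lower), and with the block within genotype, chosen after seeing the data, 19 (3 higher, 16 lower). The count was 0, 0 and 15 without mpglr-7 intact replicate 1, 2 and 3, and 0, 4 and 1 without mpglr-7 systemic replicate 1, 2 and 3, and it was 36 without replicate 3 of both intact groups, chosen after seeing the data. Of the 5 genes named by the rule, 5, 5 and 1 lost their call without mpglr-7 intact replicate 1, 2 and 3 and 5, 2 and 4 without systemic replicate 1, 2 and 3, with adjusted p up to 0.211. In a fit of only the groups compared 5 of the 5 lost their call (adjusted p up to 0.567), and 0 genes passed in all. With upper-quartile scaling 4 genes passed, 1 higher (25%, against 14.3%). Lists lower were ABA and LEA (median -0.34; 3.02e-06, adjusted p = 0.667 with an estimated correlation), bHLH (0.000636; 0.296), receptor-like kinase (0.00332; 0.667), auxin (0.00332; 0.302), WRKY (0.00589; 0.351) and jasmonate genes (0.0263; 0.351), where the last value is the adjusted p with an estimated correlation. Over the 28 lists 0 genes were higher and 1 lower, or 1 and 7 adjusted over the list alone. By fry 0 of the 28 lists passed.

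Between damaged and systemic tissue of mpglr-7, MpDIR42 (6.08), MpDIR39 (5.98), MpBHLH4 (5.40), MpERF21 (5.14, adjusted p 8.41e-14) and MpPPO31 (5.07) rose, and MpCE8.10 (-2.11), MpCYP78-like1 (-1.97), MpPOD7 (-1.86), MpTPS6 (-1.79, adjusted p 6.75e-07) and MpH3.1d (-1.45) fell. In total 2147 genes were higher and 3595 lower (48.75%), and 2698 and 2657 with median scaling, where 50.4% of calls were higher against 37.4%. With the replicate number as a block across genotypes 6232 genes passed, and with the block within genotype, chosen after seeing the data, 6340. Of the 28 lists, 10 were higher and 3 lower, the same 13 as in WT, and WRKY genes passed with an estimated correlation (2.09e-08, adjusted p = 0.0278 with an estimated correlation). For the other 12 lists the adjusted p with an estimated correlation ran from 0.0898 for dirigent genes to 0.576 for ABA and LEA genes. Over the 28 lists 259 genes were higher and 243 lower, or 260 and 244 adjusted over the list alone. The peroxidase list (0.0206) was lost with upper-quartile scaling (0.0537) and, with the pathogenesis-related list, among genes of mean FPKM of at least 5 (0.975 and 0.602; 0.00299 to 0.975 and 0.00635 to 0.602 over 6 alternatives).

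**Figure D4:**
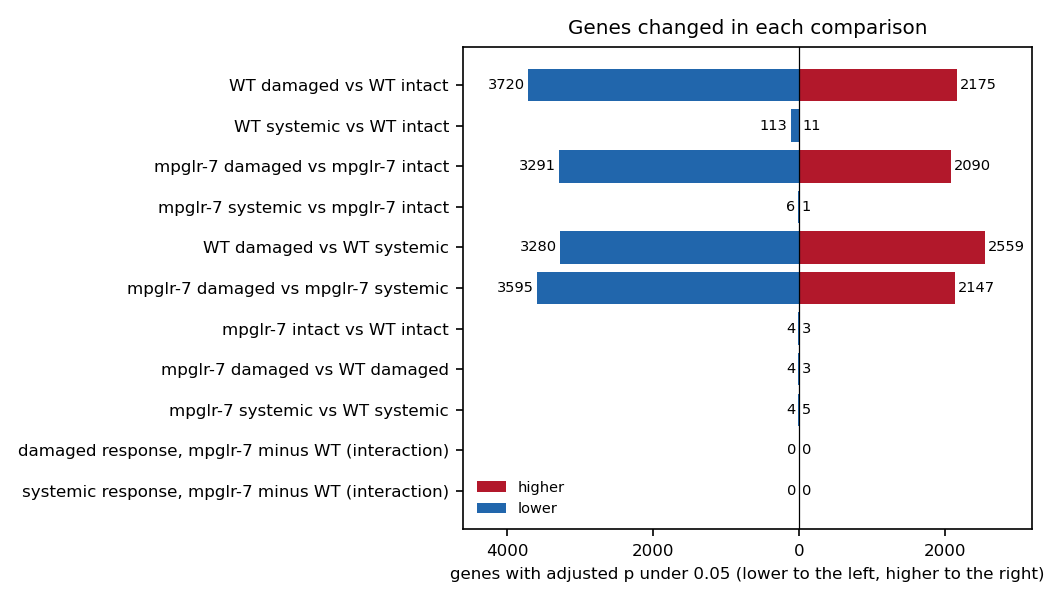
Number of genes with an adjusted p under 0.05 in each of the 11 comparisons, lower to the left and higher to the right, from groups of 3 libraries. Comparisons of damaged with intact or systemic tissue within a genotype call 5381 to 5895 genes, those of systemic with intact tissue 124 and 7, and the interactions 0.

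To ask where the genotypes themselves differed, mpglr-7 was compared with WT in each tissue state. It was the only mutant line sampled, so the loss of MpGLR cannot be told apart from other changes of that line. MpTPS6 (Mp3g13150) was higher in mpglr-7 intact (1.86, SE 0.183, adjusted p 0.000137) and systemic tissue (2.06, SE 0.183, adjusted p 3.23e-05), and in damaged tissue stood at 0.87 (adjusted p 0.167). MpCupin53 was higher in systemic tissue (1.15, SE 0.177, adjusted p 0.0113). Mp1g01040 was lower in intact (-1.57), damaged (-1.69) and systemic (-1.53) tissue, as was Mp5g06020 (-2.18, -2.26 and -1.64), and Mp2g13100 was higher in all 3 (0.69, 1.35 and 0.77). The values of MpTPS6 in damaged and of Mp2g13100 in systemic tissue are given by choice after they were seen. The counts were 3 higher and 4 lower in intact, 3 and 4 in damaged and 5 and 4 in systemic tissue, 13 genes in all, and 208, 600 and 564 genes had an unadjusted p under 0.05, with 589 expected by chance. The 208 in intact tissue lie far below that number, so the few calls there do not show that the genotypes are alike.

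Calls between genotypes were 4 without WT intact replicate 2 and 4 without mpglr-7 intact replicate 2 in intact tissue, 4 without WT damaged replicate 3 in damaged tissue, and 4 without WT systemic replicate 2 in systemic tissue. With quantile, upper-quartile or median scaling 3 of 5 calls in intact tissue were higher (60%, against 42.9%). In a fit of the intact groups alone 0 genes passed, and MpTPS6, Mp1g01040, Mp5g06020 and Mp2g13100 had adjusted p of 0.314 to 0.327, the highest over their alternatives. Mp5g06020 in systemic tissue lost its call without WT systemic replicate 1 or 2 and without mpglr-7 systemic replicate 1 or 3 (adjusted p up to 0.0969). MpCupin53 lost its call without WT systemic replicate 2 or 3 and without mpglr-7 systemic replicate 1 or 2 (adjusted p up to 0.114).

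Among the lists, ABA and LEA genes were higher in mpglr-7 intact tissue (median 0.18; 1.99e-06, adjusted p = 0.885 with an estimated correlation) and lower in mpglr-7 damaged tissue (-0.34; 1.07e-06, adjusted p = 0.708 with an estimated correlation). Calcium signalling genes were lower in mpglr-7 damaged tissue (-0.12; 0.00148, adjusted p = 0.708 with an estimated correlation). Peroxidase (0.000766), polyphenol oxidase (0.00704), cell cycle (0.0108), cell wall (0.0108), dirigent (0.0113) and receptor-like kinase (0.0153) genes were higher there, each with adjusted p = 0.708 with an estimated correlation. Of these, the polyphenol oxidase (0.954, range 0.0109 to 0.954 over 6 alternatives), cell cycle (0.258, range 0.00442 to 0.258), dirigent (0.254, range 0.0107 to 0.254) and receptor-like kinase (0.0997, range 0.0126 to 0.0997) lists were lost among genes of mean FPKM of at least 5. In mpglr-7 systemic tissue histone (-0.16; 4.47e-08), cell cycle (-0.17; 5.83e-05) and terpene synthase-like genes (-0.22; 0.00134) were lower and peroxidase genes higher (0.15; 0.00445), with adjusted p = 0.578, 0.578, 0.281 and 0.78 with an estimated correlation. With quantile, upper-quartile and median scaling, oxylipin (0.0328, 0.0222 and 0.0271) and cell wall genes (0.0281, 0.00939 and 0.0123) also passed there as higher. Dirigent genes did so with upper-quartile scaling (0.0426). Single list genes numbered 0 higher and 0 lower in intact and damaged tissue and 1 and 0 in systemic tissue, or 0 and 0, 4 and 2, and 4 and 0 adjusted over the list alone. The cell cycle call in systemic tissue was lost among genes of mean FPKM of at least 5 (0.0893, range 0.000154 to 0.0893 over 6 alternatives). By fry 0 of the 28 lists passed between genotypes in each tissue state.

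Whether MpGLR alters the wound response is asked by the difference of the responses, with mpglr-7 as the only mutant line. Of 2175 genes higher in WT damaged tissue 1868 were also higher in mpglr-7 (386 expected if calls were independent), of 3720 lower genes 2905 were also lower (1039.4 expected), and 0 were called in opposite directions. Across the 11778 genes, which are not independent replicates, the damaged responses of the genotypes correlated with r = 0.962 and rho = 0.906, with 88.4% of genes changing in the same direction, and the systemic responses with r = 0.498 and rho = 0.446, with 63.1%. Without WT intact replicate 3 the systemic r was 0.294. Same-numbered intact libraries of the genotypes tended to deviate together, so the systemic responses of the genotypes may not be independent. In limma's interaction test 0 genes differed in the damaged response (smallest adjusted p 0.226; 297 genes with an unadjusted p under 0.05) and 0 in the systemic response (smallest adjusted p 1; 358 genes), against 589 expected by chance. Counts this far below the expected one mean that p-values ran high, so 0 calls do not show that the responses are equal. The median SE of the differences between responses was 0.149, against 0.105 for a single response. Of simulated log2 differences of 0.5, 29.4% were recovered in the damaged and 22.1% in the systemic interaction, with libraries simulated as independent.

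The held-out index gave the size of the WT response in libraries that had no part in choosing the genes. Genes higher in WT damaged tissue (1233 to 1902 genes) rose by a mean log2 of 1.21 ± 0.252 in WT and 1.21 ± 0.281 in mpglr-7 (n = 3 each, exact 2-sided permutation p = 1). Genes lower in WT damaged tissue (1482 to 2640 genes) were at -0.67 ± 0.097 in WT and -0.58 ± 0.067 in mpglr-7 (n = 3 each, exact 2-sided permutation p = 0.3, smallest possible 0.1). By replicate number mpglr-7 lay above WT in 3 of 3 (by 0.102, 0.109 and 0.053). Both indices of a number were means over the same genes, and these genes differed between numbers (2043, 1482 and 2640 lower genes). The SDs above therefore include the difference between gene sets, and the permutation test ignores this pairing by genes. The libraries themselves did not pair by number in the damaged groups of the genotypes (correlations of deviations 0, -0.08 and 0.4). An exact sign-flip test gave p = 0.25, its smallest possible value. Other choices of genes were made after seeing the data. The 100 genes of smallest p among those lower in WT stood at -1.26 ± 0.052 in WT and -1.07 ± 0.049 in mpglr-7 (difference 0.191, n = 3 each, exact 2-sided permutation p = 0.1, the smallest possible). For the 100 chosen in mpglr-7 the values were -1.16 ± 0.087 and -1.04 ± 0.06 (difference 0.125, n = 3 each, exact 2-sided permutation p = 0.1). Each difference was above 0 for 3 of 3 numbers, with the same limit on pairing by number. The 100 genes among those higher rose by 3.74 ± 0.141 in WT and 3.78 ± 0.283 in mpglr-7 when chosen in WT (n = 3 each, exact 2-sided permutation p = 0.9), and by 3.45 ± 0.182 and 3.52 ± 0.178 when chosen in mpglr-7 (n = 3 each, exact 2-sided permutation p = 0.6).

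In systemic tissue 0 genes passed in limma when genes were chosen for the index in WT systemic and intact libraries without the replicate measured, 2 libraries per group, so no index was formed from genes that passed. For the 100 genes of smallest p among those higher in WT systemic tissue, chosen after seeing the data, the index of mpglr-7 minus that of WT was -0.11 (n = 3 each, exact 2-sided permutation p = 0.3). The 113 genes lower in WT systemic tissue had a median of -0.56 in WT and -0.27 in mpglr-7, where 111 were below 0, but these genes were chosen in the WT libraries. The WT damaged and systemic responses correlated with r = 0.085 and those of mpglr-7 with r = 0.154. Their covariance was 0.0117 in WT, against 0.0102 in simulations in which only the shared intact libraries tied them, and 0.0175 in mpglr-7, against 0.0103. The simulations leave out that same-numbered libraries deviated together within a genotype, so the difference from them is not read as a shared response.

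**Figure D5:**
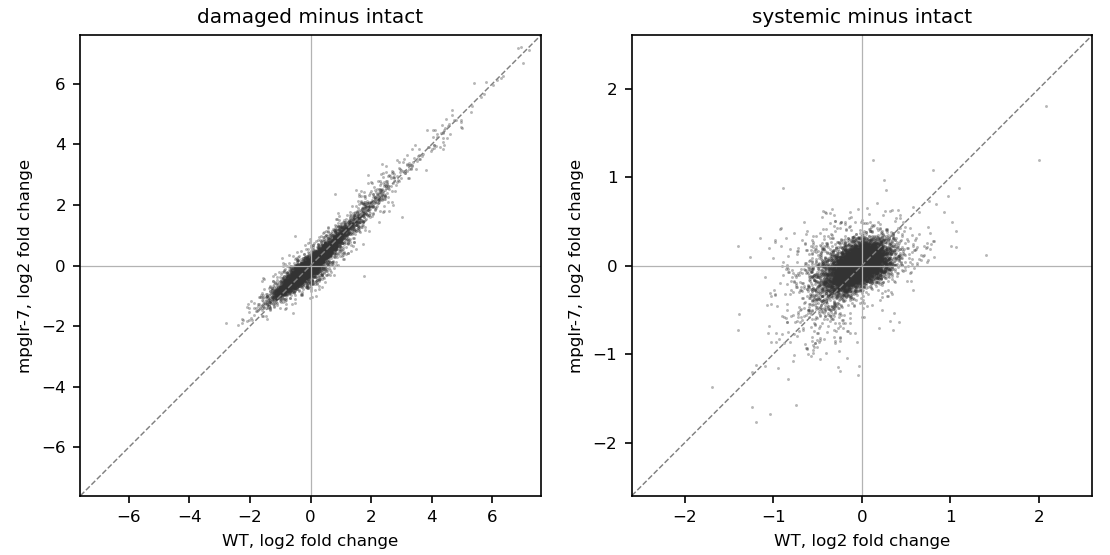
Log2 fold change of each of 11778 genes (points) in mpglr-7 against that in WT, for damaged minus intact (left) and systemic minus intact tissue (right), with dashed lines at equality. The damaged responses lie along the line (r = 0.962), and the systemic responses spread around 0 (r = 0.498).

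As lists, the damaged response was more positive in mpglr-7 for peroxidase (median 0.20; 3.09e-05) and polyphenol oxidase genes (0.13; 0.0136) and more negative for ABA and LEA genes (-0.60; 9.88e-14), each with adjusted p = 0.813 with an estimated correlation. The systemic response was more positive for peroxidase genes (0.27; 0.000213, adjusted p = 0.697 with an estimated correlation). It was more negative for histone (-0.13; 3.94e-08), ABA and LEA (-0.19; 2.39e-05), terpene synthase-like (-0.32; 3.28e-05) and cell cycle genes (-0.09; 0.00098), with adjusted p = 0.683, 0.697, 0.0812 and 0.697 with an estimated correlation. Single list genes numbered 0 in both interactions (limma), or 1 higher in damaged and 0 in systemic tissue adjusted over the list alone. By fry none of these lists passed (adjusted p 0.707 for damaged and 0.511 to 0.783 for systemic responses). Among genes of mean FPKM of at least 5 the polyphenol oxidase (0.774, range 0.00601 to 0.774 over 6 alternatives) and cell cycle (0.14, range 0.00189 to 0.14) calls were lost.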

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

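The list tests of the differences between genotypes and the regroupings of libraries were fixed in advance, as was the adjusted p of the LEA list without single libraries. The tests of the index of 100 genes, with quantile normalization of that index, of the spread of the LEA list and of the size of its difference without single libraries were chosen after the result was seen, as were median scaling and the use of the genes of mean FPKM of at least 5, a setting fixed in advance, as a test.

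These results were picked out because the responses of WT and mpglr-7 differed in a list test (camera, preset correlation), although 0 single genes did by limma (297 and 358 at an unadjusted p under 0.05 in the damaged and systemic interactions). In damaged tissue the response of ABA and LEA genes was more negative in mpglr-7 (median difference -0.60, adjusted p 9.88e-14), that of peroxidase genes more positive (0.20, adjusted p 3.09e-05) and that of polyphenol oxidase genes more positive (0.13, adjusted p 0.0136). In systemic tissue the responses of histone (-0.13, adjusted p 3.94e-08), ABA and LEA (-0.19, adjusted p 2.39e-05), terpene synthase-like (-0.32, adjusted p 3.28e-05) and cell cycle genes (-0.09, adjusted p 0.00098) were more negative in mpglr-7 and that of peroxidase genes more positive (0.27, adjusted p 0.000213). With an estimated correlation none passed (adjusted p 0.813 for each of the 3 lists in damaged tissue, and 0.0812 to 0.697 for the 5 in systemic tissue), nor did any by fry (0.707, and 0.511 to 0.783).

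The LEA and ABA genes rose in WT damaged tissue as a list with the preset correlation (26 of 72 genes higher and 4 lower), lost that call with an estimated correlation (adjusted p = 0.559) and did not pass in mpglr-7, and the difference itself passed with the preset correlation only. Whether 1 library carries it stays open: with each of the 12 left out in turn the adjusted p stayed at or below 5.95e-07, a bound set in advance that decides nothing, since the preset correlation takes the genes as nearly independent, and the difference of the list mean was -0.497 (SE 0.429) with all libraries and -0.278 (SE 0.418, without WT intact replicate 2) to -0.725 (SE 0.412, without mpglr-7 intact replicate 1) with 1 of the 12 left out. Same-numbered damaged minus intact differences of the list mean were 0.852, 0.723 and 0.28 in WT (0.618 ± 0.3) and 0.267, 0.364 and -0.268 in mpglr-7 (0.121 ± 0.341), which overlap (n = 3 each, exact 2-sided permutation p = 0.2). By replicate number mpglr-7 lay below WT by 0.585, 0.359 and 0.548, below in 3 of 3. But numbers pair the genotypes at most in intact tissue, weakly for number 2 (correlation 0.12), and an exact sign-flip test of 3 pairs gives no p under 0.25. The spread between libraries therefore stays open, as do the intact libraries, where the list was higher in mpglr-7 (median 0.18, adjusted p 1.99e-06, adjusted p = 0.885 with an estimated correlation) and which both interactions share, and a weaker LEA response in mpglr-7, which may underlie the pattern and was not tested apart from them.

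The 100 genes of smallest p among those lower in WT systemic tissue, chosen without the replicate measured, stood at -0.50 ± 0.113 in WT and -0.19 ± 0.200 in mpglr-7 (difference 0.311, n = 3 each, exact 2-sided permutation p = 0.1, the smallest possible). Scaling of the FPKM values as the whole cause stays open. With quantile normalization the difference was 0.247, above the pooled SD of 0.172 that was set as the bar. That bar is 1 SD of single values, and the exact 2-sided permutation p was 0.2, so the value decides nothing. Without mpglr-7 replicate 1, 2 or 3 the difference was 0.415, 0.215 and 0.303, above the pooled SD (an intact library and the systemic one of its number leave together). The difference kept its sign, with the genes and the WT values unchanged. But the bar decides no more here than above, since 2 mpglr-7 values were left against 3 of WT. A single mpglr-7 library therefore stays open. A single WT library stays open: without WT intact replicate 1 or 2 or WT systemic replicate 1 the difference was -0.137, 0.091 and -0.086, within the pooled SD. These fits left 1 library in that group to choose genes, assumed to vary like the others. The choice of the genes in WT libraries stays open and is consistent with the values: for 100 genes chosen in mpglr-7 the difference was 0.042, within the pooled SD of 0.105 (n = 3 each, exact 2-sided permutation p = 0.7). A weaker systemic response of mpglr-7 stays open and untested by any gene of its own, since 0 genes passed the systemic interaction (limma, 358 at an unadjusted p under 0.05).

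More genes were lower than higher in WT damaged tissue, with 36.9% of calls higher. Noise in genes of low FPKM is argued against, since among genes of mean FPKM of at least 5 the higher share was 37.6%. A shift in composition stays open: genes at least 2-fold higher in damaged tissue took 2.33 ± 0.12% of the FPKM in WT intact and 9.40 ± 0.46% in WT damaged libraries, but the higher share of 49% with median scaling, by factors of 0.946 to 1.063, decides nothing, since centring the typical gene largely fixes it. With quantile normalization and upper-quartile scaling the share was 37.9% and 34.1%. The median log2 change over all 11778 genes was -0.103. Among the 1046 calls of at least 2-fold, 71.2% were higher, so the excess of lower calls lay among smaller changes. A wound response with more genes lower than higher stays open and was not tested apart from a shift in composition.

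Regrouping 3 against 3 libraries gives 10 splits, so their share is never under 0.1. Mixing damaged libraries with intact or systemic ones also adds the wound response to the spread within groups. Few calls in the other splits of those comparisons were thus built in and lend no support. In WT damaged against intact tissue 1 of 10 splits gave as many genes as the real 5895, and the highest other gave 1. In 7 further comparisons of groups, 1 of 10 splits gave as many as the real one and the highest other gave 0, against 124 in WT systemic, 5381 in mpglr-7 damaged, 7 in mpglr-7 systemic, 5839 and 5742 in damaged against systemic tissue of WT and mpglr-7, and 7 and 9 between genotypes in damaged and systemic tissue. Between genotypes in intact tissue 2 of 10 splits gave at least the real 7, and the highest other gave 388. That split set WT intact replicates 1 and 2 and mpglr-7 intact replicate 1 against the other 3 libraries, which points to a structure of the intact libraries that their genotype does not follow. For the interactions, any regrouping reaches a real count of 0, so the regroupings say nothing about chance: 100 of 100 drawn regroupings gave at least the real 0 genes in damaged tissue, where the highest other gave 358, and 100 of 100 in systemic tissue, where it gave 65.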

How the results depend on the processing

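The block within genotype, median scaling, leaving out replicate 3 of both intact groups, unsummed transcript models, genes with 1 model, the index of 100 genes and the index of genes chosen in mpglr-7 were settings chosen after seeing the data; all others were fixed in advance. Over 26 main results, 265 recomputed values stayed within 1.5 times the reported count or within the spread, and 62 did not. The cause was not tested unless the setting itself shows it.

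A log2 change of at least 1 left 1046 genes in WT damaged, 12 in WT systemic, 913 in mpglr-7 damaged and 1 in mpglr-7 systemic against intact tissue, 1099 and 914 in damaged against systemic tissue of WT and mpglr-7, and 4 between genotypes in intact tissue, as a stricter threshold must. A fit of only the groups compared gave 5 genes in WT systemic, 0 in mpglr-7 systemic, and 0, 3 and 22 between genotypes in intact, damaged and systemic tissue. The replicate block gave 294 in WT systemic, where the 124 reported genes were all kept, 20 in mpglr-7 systemic, where all 7 were kept, and 13 and 15 between genotypes in damaged and systemic tissue. The block within genotype gave 335 and 19 in WT and mpglr-7 systemic. Without replicate 3 of both intact groups the counts were 352 in WT systemic, 36 in mpglr-7 systemic and 4 between genotypes in intact tissue. A mean FPKM of at least 5 gave 4 and 5 between genotypes in damaged and systemic tissue, with fewer genes tested, and upper-quartile scaling gave 4 in mpglr-7 systemic. The interactions gave 0 genes in limma under every setting run.

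With 1 library left out, counts ranged from 18 (without WT systemic replicate 3) to 287 (without WT intact replicate 3) in WT systemic and from 0 to 15 in mpglr-7 systemic, and from 4 to 5, 4 to 7 and 4 to 8 between genotypes in intact, damaged and systemic tissue. They ranged from 5181 to 5642 in WT damaged and 4725 to 4975 in mpglr-7 damaged. The correlation of the genotypes' responses ranged from 0.938 to 0.967 in damaged and from 0.294 to 0.583 in systemic tissue, and the systemic value was 0.429 with a pseudocount of 0.1. The difference between genotypes in the index of genes lower after damage was 0.191 with 100 genes, against 0.088. With an estimated correlation between genes the number of lists passing was 0 in WT damaged, 0 in WT systemic, 1 in mpglr-7 damaged, 0 in mpglr-7 systemic, 1 in each comparison of damaged with systemic tissue, 0 in each tissue state between genotypes and 0 in both interactions. Between genotypes in damaged tissue 4 lists passed among genes of mean FPKM of at least 5.

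For named genes, 526 results gave 9017 values under other settings, of which 8706 stayed on the same side of the threshold, 311 were no longer past it, and 0 changed direction. The genes were named because they passed in the same data, so these counts favour values that hold. In a fit of only the groups compared, calls were lost for 17 of 18 named genes in WT systemic and 5 of 5 in mpglr-7 systemic tissue. Between genotypes in intact tissue 5 of 5 were lost. MpGLR settings were not run, since the gene is not analysed here. Depth is unknown, so a gene of low FPKM without a call may be one that was not detectable; among genes of mean FPKM of at least 5 the counts between genotypes were 4 and 5 against 7 and 9.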

Other observations

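The gene sets in this part and the tests of families were chosen after the result was seen. Of 12 genes with a symbol of the shikimate and phenylalanine pathway, which supplies phenylpropanoid synthesis, 8 rose and 2 fell in WT damaged tissue (median 1.17) and 9 rose and 2 fell in mpglr-7 (median 1.07). The set was picked after its genes were seen to rise, so no test of it is given. In WT and mpglr-7 the log2 changes were 2.44 and 2.30 for MpDAHP, whose enzyme opens the pathway, 2.37 and 2.37 for the chorismate synthase gene MpCS, 1.67 and 1.65 for MpEPSPS and 2.06 and 2.25 for the arogenate dehydratase gene MpADT4. The counterpart genes MpSK2 (-0.37 and -0.50) and MpADT1 (-0.23 and -0.24) fell. In systemic tissue 0 of the 12 passed in limma in either genotype (medians -0.04 and 0.01). With quantile, upper-quartile and median scaling 8 to 9 of the 12 were higher in WT and 9 in mpglr-7.

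Families of at least 5 tested members, defined by the stem of the symbol, were compared with the other genes with a symbol (102 families, 2340 genes, Fisher's exact test, 1-sided, adjusted over families, treating genes as independent). Chosen after the result was seen, these tests only describe the families. Of 12 MATE transporter genes, 8 rose and 3 fell in WT damaged tissue (66.7%, adjusted p 0.0456) and 8 rose and 2 fell in mpglr-7 (adjusted p 0.0428). Of genes with a symbol, 24.1% rose in WT and 23.1% in mpglr-7. Among the MATE genes that rose were MpMATE15 (2.77 in WT, 2.47 in mpglr-7), MpMATE1 (1.80 and 1.83) and MpMATE7 (1.63 and 1.64), with 8 higher under each of the 3 other scalings in both genotypes. Of 71 pentatricopeptide repeat (PPR) genes, which code for RNA-binding proteins of organelles, 34 fell in mpglr-7 damaged tissue (47.9% against 27.5%; adjusted p 0.00904) and 34 in WT, where the family did not pass (adjusted p 0.0896). Under the other scalings 31 to 37 fell in WT and 29 to 38 in mpglr-7.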
